A study of Homo sapiens with 9 samples.

How the data were processed

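Total RNA from 9 samples of the human embryonic stem cell line HSF-6 was measured on 9 Affymetrix arrays of the human U133 Plus type. Per the labels, sublines (8) and (S9) were collected after 11 passages and grown for 6 days. The RNA was amplified with the MessageAmp Premier kit and carried biotin. There were 3 groups of 3 arrays: HSF-6(8) control, HSF-6(8) with butyrate and DZNep, and HSF-6(S9) with butyrate and DZNep. Butyrate inhibits histone deacetylases. DZNep, 3-deazaneplanocin A, inhibits S-adenosylhomocysteine hydrolase (AHCY) and lowers the Polycomb methyltransferase EZH2.

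The deposited values are signal intensity per probe set on a linear scale. The authors made them with Affymetrix Expression Console and MAS5, whose versions are not given in the sources used here. MAS5 summarises perfect match and mismatch probes and scales each array. On every array the mean without the top and bottom 2% of probe sets lay between 500.061 and 500.076. The deposited table held 54675 probe sets with no detection calls, of which 62 were controls. Of the others, 41091 mapped to a single gene, 1801 to several genes and 11721 to none. Current gene symbols were matched by Entrez number for 41037 of the single-gene probe sets and 54 had no match.

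For the tests, 16 was added to each value before taking log2, so fold changes of dim genes are understated. A probe set was kept if at least 3 of the 9 arrays lay above their own median, which left 29328 probe sets, 24772 of them with a single gene. The probe set with the highest mean stood for its gene, which gave 13516 genes. 6533 of these genes had several kept probe sets. XIST, TSIX and genes of the Y chromosome were left out. POU5F1 could not be tested because its probe sets map to several genes.

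All 9 arrays entered a single linear model with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). It had 6 residual degrees of freedom and 3.50 prior degrees of freedom. The 3 comparisons were treated minus untreated HSF-6(8), treated HSF-6(S9) minus treated HSF-6(8), and treated HSF-6(S9) minus untreated HSF-6(8). P-values were two-sided and adjusted by Benjamini-Hochberg over the 13516 genes of each comparison. A gene was called when its adjusted p was under 0.05 and its change was at least 2-fold. Simulated data with 200 changed genes in each of 20 runs were used to test the calling steps. Simulated arrays varied independently, without the correlation between real arrays given below, and changes were added on the log2 scale. The 2-fold minimum itself drops true 2-fold changes that are estimated below it.

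Gene lists numbered 30: pluripotency network, naive and primed state, neuroectoderm, mesoderm and primitive streak, endoderm, trophoblast, fibroblast and stromal markers, HOX genes, Polycomb complexes, histone lysine methyltransferases and demethylases, histone deacetylases and sirtuins, DNA methylation and TET enzymes, methionine metabolism, fatty acid oxidation, cholesterol synthesis, glycolysis, histone genes, metallothioneins, cell cycle inhibitors and p53 targets, proliferation, imprinted genes, germline genes, X-linked cancer-testis genes, TGF-beta, Nodal, BMP and FGF responses, WNT signalling, apoptosis, endoplasmic reticulum and oxidative stress, keratins with epithelial adhesion, and all tested X-linked genes. Each list was tested with camera at a preset correlation of 0.01, adjusted over 90 tests. Beside it stand camera with an estimated correlation, fry, and the members called when adjusted over the list alone. In the first comparison the estimates were -0.20, -0.145 and -0.03 for cancer-testis, germline and WNT genes, and 0.061 to 0.332 for the other called lists. The camera p of the cancer-testis list still rose from 7.95e-06 to 0.00396 without adjustment. A call lost with an estimated correlation therefore does not by itself show that members are correlated. The overlap of the contrasts that share the control arrays was set against 100 simulations of unchanged groups with shared controls, in which the arrays of a group varied independently. The prime marks of the titles, which the labels do not explain, were checked as a pairing by the correlation of arrays after removing group means. Arrays of the same mark had r of 0.21, 0.26 and 0.49 between untreated and treated HSF-6(8) and 0.18, 0.20 and 0.25 between the treated sublines, all above 0.1, but -0.03, 0.08 and 0.34 between untreated HSF-6(8) and treated HSF-6(S9). The first and second arrays of untreated and treated HSF-6(8) correlated as much across marks (0.26 and 0.32).

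Comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, or 3 of each in the comparison across sublines and treatment. From each list it took up to 4 called members, or else the 2 largest changes as values. It always named SOX2, NANOG, EZH2, AHCY, HDAC1, DNMT3B and, where testable, POU5F1. Genes named outside it are marked as chosen after their values were seen.

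The alternatives tried were pseudocounts of 1 and 64, no filter and a filter at the 75th percentile, quantile normalization, median centring, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust, fits of only the 2 groups compared, a replicate block, no fold minimum, an adjusted p under 0.01, treat at 1.5-fold, an unmoderated test with unequal variances, and leaving out each array in turn. Alternatives added after seeing the data were the third arrays as a batch block, only the first and second arrays, array weights, and leaving out 3 arrays that stood apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.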

Results

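The data are gene expression levels of the human embryonic stem cell line HSF-6, measured on 9 arrays in 3 groups of 3. HSF-6(8) cells were grown without and with butyrate and DZNep, and HSF-6(S9) cells were grown with both compounds. The median signal of an array lay between 64.8 and 82.9, and the number of arrays limits the precision of every value. The labels do not say whether the 3 arrays of a group are separate cultures, and their titles mark them only with primes. The p-values therefore measure the spread between these samples, which may be partly technical. The third arrays of the 3 groups had 18S ribosomal RNA signals of 963, 850 and 1517, against 385 to 542 on the other arrays. After removing group means, the third arrays correlated with each other (r from 0.25 to 0.49). Their correlations with the first and second arrays of the other groups were negative (-0.38 to -0.06). This largely follows from removing the mean of 3 arrays and is not a separate observation. The labels name no batch. Values below are signal as mean ± SD (n = 3 arrays) and log2 fold change ± SE from limma.

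The first comparison asks which genes butyrate and DZNep changed in HSF-6(8). Treated cells had 101 genes higher and 13 lower than controls, and many of the genes that rose had little signal in control cells. The zinc finger gene ZNF682 rose from 7.35 ± 3.48 to 784 ± 209 (n = 3 arrays), a log2 fold change of 5.08 ± 0.30 with 16 added to each value. Its control signal is so low that the size of the fold depends on that number, with 6.61 when 1 and 3.54 when 64 was added. DKK1, which encodes a secreted inhibitor of WNT signalling, rose from 176 ± 46.9 to 3171 ± 490. NNAT, an imprinted gene expressed in the developing brain, rose from 39.1 ± 5.80 to 707 ± 111, and the X-linked gene BEX5 rose from 33.5 ± 2.93 to 560 ± 86.7. Among the genes that fell, MBD3L2, a relative of the methyl-CpG-binding protein gene MBD3, went from 207 ± 55.9 to 6.24 ± 1.65, a log2 fold change of -4.84 with 1 and -1.93 with 64 added to each value.

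Of the 10 largest rises, GPAT2, an acyltransferase gene of glycerolipid synthesis, had a log2 fold change of 3.93 ± 0.24 (limma adjusted p = 6.82e-05). The second zinc finger gene in this set, ZNF626, rose by 3.78 ± 0.32, although its probe sets ranged from 0.81 to 3.78. CST1, which encodes a secreted cystatin that inhibits cysteine proteases, rose by 3.65 ± 0.39 to a signal of 5472 ± 501. The rises of ASTE1 and of the carbonyl reductase gene CBR1 were 3.57 ± 0.28 and 3.47 ± 0.36, from control signals of 3.30 ± 1.70 and 6.02 ± 4.63; with 1 and 64 added to each value they were 5.71 and 2.05 for ASTE1 and 5.19 and 2.06 for CBR1, so the order of these rises is not fixed. GPAT2, from a control signal of 9.74 ± 4.20, had 2.57 with 64 added. ZNF626 started from 16.1 ± 9.49, so its fold depends on the added number as well. Adjusted p was 6.82e-05 for ZNF682 and DKK1, 0.000427 for NNAT and 3.63e-05 for BEX5. DPPA5, a gene of early embryonic and germ cells, rose by 3.69 ± 0.57 (adjusted p = 0.0201) with a treated signal of 3435 ± 1843. Its adjusted p was 0.057 to 0.0806 without any of the control arrays or without the second or the third treated HSF-6(8) array, each left out alone.

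Fewer genes fell. GRPR, the receptor of gastrin-releasing peptide, fell from 743 ± 217 to 139 ± 7.22 with a log2 fold change of -2.25 ± 0.23 (adjusted p = 0.00178). FLT1, a receptor of vascular endothelial growth factor, fell from 1052 ± 43.7 to 243 ± 6.33 (-2.05 ± 0.16, adjusted p = 0.000324), while another of its probe sets gave 0.19. The metalloprotease gene ADAMTS8 fell by 2.15 ± 0.26 on the log2 scale. The other named falls were ART3, EVA1C, GPR176, CFAP95, PCDHB16 and NALF1, with log2 fold changes from -1.92 to -1.40. With 1 added to each value ART3 had -2.89 and was not called (adjusted p = 0.0858), nor was GPR176 (0.0616), and with 64 added PCDHB16 (-0.86) and NALF1 (-0.99) fell short of 2-fold. These last 6 genes each lost their call without some single array, with adjusted p from 0.0504 to 0.162. The arrays were the control arrays, any treated HSF-6(8) array or the first or second HSF-6(S9) array, depending on the gene.

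**Figure D1:**
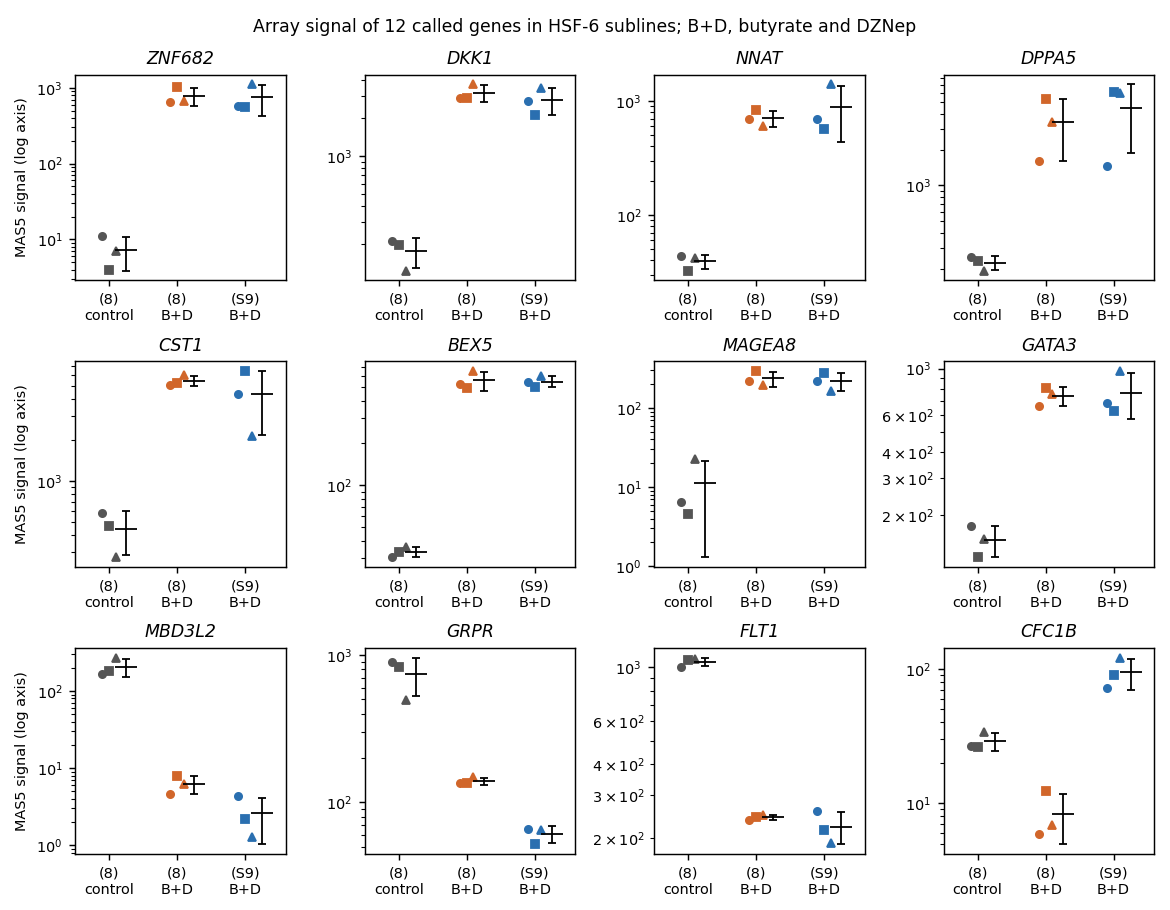
MAS5 signal (log axis, a separate range in each panel) of 12 called genes on each of the 9 arrays, as circles, squares and triangles for replicates 1, 2 and 3, with a horizontal tick at the group mean and bars of 1 SD. B+D is butyrate and DZNep; ZNF682 had a mean of 7.35 in control and 784 in treated HSF-6(8) cells, and for CFC1B the HSF-6(S9) arrays lie above all others.

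Marker lists of differentiated lineages were higher by camera, and fewer of them by fry. The endoderm list had 18 tested members, all with a positive change and a median log2 fold change of 0.97 (camera adjusted p = 2.69e-10; adjusted p = 0.261 with an estimated correlation; fry adjusted p = 0.0750). None was called over all genes in the model without a block, and 8 were called when adjusted over the list alone. Its largest values were 3.04 ± 0.63 for the transcription factor gene GATA6 (adjusted p = 0.0705) and 2.78 ± 0.72 for TTR, which encodes transthyretin (adjusted p = 0.145). Without the third treated HSF-6(8) array GATA6 was called (2.13, adjusted p = 0.00701), as it was without the first (3.68, adjusted p = 0.03). With the third arrays as a batch block GATA6 (adjusted p = 0.0296) and TTR (0.00773) were called, and with a replicate block as well (0.0484 and 0.0127). The third treated array had an endoderm median of 2.46 over the control mean, against 0.59 and 0.75 on the other treated HSF-6(8) arrays.

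Neuroectoderm markers had a median of 0.64 over 11 members (camera adjusted p = 0.0023; adjusted p = 0.313 with an estimated correlation; fry adjusted p = 0.0696). PAX3, a transcription factor gene of the neural tube and neural crest, was the 1 member called (2.85 ± 0.51, adjusted p = 0.0405), and 4 were called when adjusted over the list alone. The PAX3 probe sets ranged from -0.12 to 2.85, and with 64 added to each value PAX3 was not called (2.07, adjusted p = 0.0533). Of the 12 trophoblast markers, GATA3, a transcription factor gene, rose from 153 ± 26.2 to 743 ± 75.2, and 2 were called when adjusted over the list alone. The trophoblast median was 0.70 (camera adjusted p = 0.00237; adjusted p = 0.261 with an estimated correlation; fry adjusted p = 0.0246). Mesoderm and primitive streak markers had a median of 0.65 over 15 members (camera adjusted p = 0.0229; adjusted p = 0.520 with an estimated correlation; fry adjusted p = 0.141). With no filter on low values the medians were 0.30 for neuroectoderm, 0.22 for trophoblast and 0.40 for mesoderm, and mesoderm was not called (adjusted p = 0.0538), nor was it with the 75th percentile filter (0.235). The 1 member called, also when adjusted over the list alone, was ID3, a target of BMP signalling, at 1.17 ± 0.20 (adjusted p = 0.0331). The mesoderm list was not called without the first control array (adjusted p = 0.0849) or without the third treated HSF-6(8) array (adjusted p = 0.194). PAX3 and ID3 each lost their call without any of the control arrays, any of the treated HSF-6(8) arrays or the first HSF-6(S9) array, with adjusted p from 0.0626 to 0.132.

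Fibroblast and stromal markers, included for other cells a culture could hold, had a median of 0.53 over 20 members (camera adjusted p = 0.0534; adjusted p = 0.729 with an estimated correlation; fry adjusted p = 0.604). None was called over all genes and 2 when adjusted over the list alone, with FN1 at 1.32 ± 0.30 (adjusted p = 0.107) and COL1A1 at 1.10 ± 0.26 (adjusted p = 0.112). With a replicate block FN1 (adjusted p = 0.0492) and the list (0.0471) were called, and with no filter on low values the list was (0.0419). With an estimated correlation the list had an adjusted p of 0.671 with that block and 0.725 with no filter. The stromal median was 1.20 on the third treated HSF-6(8) array and 0.08 and 0.13 on the other treated HSF-6(8) arrays. The list was called without the third control array (adjusted p = 0.0398), the first or second treated HSF-6(8) array (0.000985 and 0.0039), or the second or the third HSF-6(S9) array (0.0276 and 0.0341). None of these calls held with an estimated correlation (adjusted p = 0.795, 0.547, 0.700, 0.754 and 0.663 in that order) or by fry (0.728, 0.394, 0.566, 0.561 and 0.538).

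**Figure D2:**
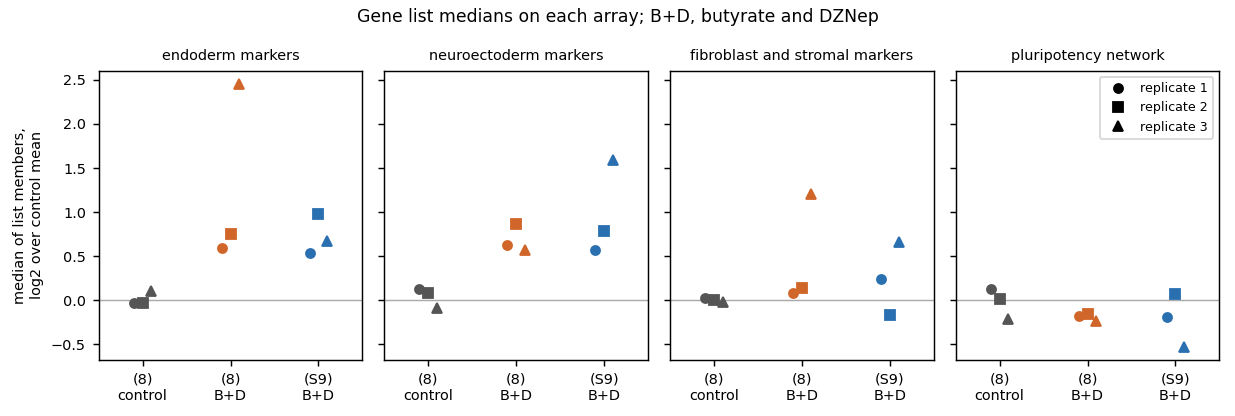
Median over list members of the log2 difference from the control mean (vertical axis) on each of the 9 arrays, for 4 gene lists, with circles, squares and triangles for replicates 1, 2 and 3. B+D is butyrate and DZNep; the third treated HSF-6(8) array lies at 2.46 for endoderm markers and 1.20 for fibroblast and stromal markers.

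Of 29 germline genes 5 and of 30 X-linked cancer-testis genes 4 passed the filter on low values, which a rise in the treated cells can itself satisfy, so their medians describe those members and not the lists. Of the 5 germline genes, DPPA5 and the piRNA pathway gene TDRD12 were called higher. TDRD12 went from 213 ± 63.5 to 863 ± 196 (1.95 ± 0.24, adjusted p = 0.00592). When adjusted over the list alone, 4 germline genes were called higher and 1 lower. Their median was 1.65 (camera adjusted p = 0.00144, and 0.229 with an estimated correlation). Fry also called these germline genes higher (fry adjusted p = 0.00079). Of the 4 cancer-testis genes, MAGEA8 rose from 11.3 ± 9.96 to 237 ± 52.4 (a log2 fold change of 4.56 with 1 and 1.99 with 64 added to each value), and 2 were called when adjusted over the list alone. The median of these 4 was 1.81 (camera adjusted p = 0.000274, and 0.229 with an estimated correlation). Fry called them higher as well (fry adjusted p = 0.000588). With no filter on low values neither list was called, with a median of 0.21 for germline (adjusted p = 0.0535) and -0.00 for cancer-testis genes (adjusted p = 0.526).

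WNT signalling genes had a median of 0.23 over 18 members (camera adjusted p = 0.0108; adjusted p = 0.246 with an estimated correlation; fry adjusted p = 0.00185). The list was not called with the mean of a gene's probe sets (0.12, adjusted p = 0.114), the 75th percentile filter (0.10, 0.127) or only the first and second arrays (0.25, 0.0539), and its median was 0.41 with no filter on low values. The 2 called members, also when adjusted over the list alone, were DKK1 and LEF1, a transcription factor gene of the WNT pathway (2.80 ± 0.50, adjusted p = 0.0405). Without the first or second control array, any treated HSF-6(8) array, or the first or second HSF-6(S9) array, LEF1 lost its call, with adjusted p from 0.0513 to 0.142, as it did with 1 added to each value (4.07, 0.0841). Among 22 imprinted genes, NNAT and NLRP2, an oocyte and early embryo gene (1.58 ± 0.23, adjusted p = 0.0164), were called, both also when adjusted over the list alone. Adjusted p of NLRP2 was 0.0585 and 0.059 without the first and the second treated HSF-6(8) array. The imprinted list itself was not called (camera adjusted p = 0.270). Of 467 X-linked genes, 8 rose and 1 fell, and when adjusted over the list alone 10 rose and 6 fell (camera adjusted p = 0.665). TCEAL2 and TCEAL7, X-linked genes of the same wider family as BEX5, rose by 3.44 ± 0.26 and 3.2 ± 0.32.

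Genes for the targets of the compounds were not called, and of the lists of chromatin regulators 1 was called by fry and 0 by camera. EZH2 changed by 0.40 ± 0.31 (adjusted p = 0.827), AHCY by 0.26 ± 0.22 (0.852), HDAC1 by 0.26 ± 0.21 (0.827) and the DNA methyltransferase gene DNMT3B by 0.07 ± 0.25 (0.989). These are RNA levels, which do not measure the activity or the protein amount of these enzymes. The lists of 25 Polycomb genes, 34 histone lysine methyltransferases and demethylases and 20 histone deacetylases and sirtuins had 0 called members, also when adjusted over the list alone. Their camera adjusted p were 0.822, 0.890 and 0.938, and their largest values were 1.28 ± 0.50 for YAF2, -0.61 ± 0.23 for PCGF5, 0.83 ± 0.26 for SETD7, 0.45 ± 0.15 for KDM6B, -0.45 ± 0.25 for HDAC9 and 0.41 ± 0.35 for HDAC5. The 19 DNA methylation and TET genes also had 0 called, but 2 higher when adjusted over the list alone (camera adjusted p = 0.460), with DNMT3L at 1.5 ± 0.34 (adjusted p = 0.104) and UHRF1 at 1.37 ± 0.35 (adjusted p = 0.137). Fry called this list higher (adjusted p = 0.00185; median log2 fold change 0.02), and UHRF1 was called with the third arrays as a batch block (adjusted p = 0.0054) and with a replicate block (0.0126). Of 14 histone genes, the variant histone gene MACROH2A2 rose from 339 ± 130 to 1187 ± 88.6, also when adjusted over the list alone (list camera adjusted p = 0.159). MACROH2A2 had an adjusted p of 0.0126 with all arrays, and of 0.0527, 0.0585 and 0.0571 without the first control, first treated and second treated HSF-6(8) arrays. The histone list was called without the first or second treated HSF-6(8) array (adjusted p = 0.0445 and 0.026; adjusted p = 0.618 and 0.700 with an estimated correlation; fry adjusted p = 0.406 and 0.440).

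Genes of the pluripotent state gave 0 calls among 25 members (median -0.19, camera adjusted p = 0.0955), also when adjusted over the list alone. SOX2 changed by -0.19 ± 0.26 (adjusted p = 0.944) and NANOG by -0.48 ± 0.25 (0.621). LEFTY1, an inhibitor of Nodal signalling, averaged 9799 ± 1534 in controls and 3482 ± 4122 in treated cells, and NODAL averaged 2059 ± 116 and 1724 ± 1678. Neither was called with all arrays (adjusted p = 0.257 and 0.810). Without the third treated HSF-6(8) array both were called lower (-3.16, adjusted p = 0.00288; -1.43, adjusted p = 0.00701), and so was the pluripotency list (median -0.17, camera adjusted p = 0.00359; adjusted p = 0.471 with an estimated correlation; fry adjusted p = 0.176). Naive state markers had DPPA5 as the 1 called member of 15 and 2 when adjusted over the list alone (camera adjusted p = 0.294). Primed state markers had 0 called of 18 and 1 lower when adjusted over the list alone (0.701), with CYTL1 at 1.43 ± 0.70 and NLGN4X at -1.04 ± 0.21 (adjusted p = 0.0381 with the third arrays as a batch block). ID3 was the 1 called member of the 29 TGF-beta, Nodal, BMP and FGF response genes, also when adjusted over the list alone (0.674), a list whose median of -0.06 and mean of 0.07 differ in sign. ID3 lost that call without single arrays, with adjusted p up to 0.122 without the first control array.

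Metabolic, stress and cell cycle lists had 0 called members over all genes. This held for methionine metabolism (22 tested, camera adjusted p = 0.282), fatty acid oxidation (24, 0.270), cholesterol synthesis (19, 0.281), glycolysis (21, 0.725), metallothioneins (9, 0.948), cell cycle inhibitors and p53 targets (18, 0.516), proliferation (27, 0.270), apoptosis (22, 0.948), endoplasmic reticulum and oxidative stress (23, 0.121) and HOX genes (7, 0.890). In each of these 10 lists 0 members were called when adjusted over the list alone. Of 25 keratin, claudin and adhesion genes 0 were called and 1 when adjusted over the list alone (0.281), with ZEB1, a repressor of epithelial genes, at 2.39 ± 0.48 (adjusted p = 0.0653). ZEB1 was called without the third HSF-6(S9) array (adjusted p = 0.0176) and with the third arrays as a batch block (0.0179) or a replicate block (0.0334). Without the third treated HSF-6(8) array, the proliferation list (median -0.14, adjusted p = 0.0282) and the stress list (median -0.26, adjusted p = 0.00373) were called lower by camera. Neither was with an estimated correlation (adjusted p = 0.306 and 0.251) or by fry (0.0716 and 0.0869).

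The 114 called genes were all among the 2345 genes whose arrays did not overlap between the groups (17.3%, where 10% would occur by chance). The median signal of the 101 higher genes went from 65.6 to 406, and 54 of them had a control mean below 71.5, a typical array median. Of the 41 called genes with several probe sets, 6 had probe sets that disagreed in sign. The count was 118 without the third treated HSF-6(8) array (88 higher, 30 lower). It fell to 68, 59 and 59 without the first, second and the third control array, and to 63 and 52 without the first and second treated HSF-6(8) array. With the third arrays as a batch block it was 191, and within the first and second arrays alone it was 91; the third arrays hold 1 sample per group and give no value of their own. Leaving out 3 arrays that stood apart, chosen after seeing the data, left 35 genes. Of these the first control had an ACTB signal ratio of 3' to 5' probes of 1.67 (1.18 to 1.39 on the others) and a BioB spike-in signal of 1718 (440 to 702 on the others), and the third treated HSF-6(8) and second HSF-6(S9) arrays had the lowest correlations within their groups (0.950 and 0.959). The third control, with 0.963, was kept. Without these 3 arrays the neuroectoderm (adjusted p = 0.0721) and mesoderm lists (0.285) were not called.

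The second comparison asks how the treated sublines differ. CFC1B, a gene of the family of Nodal co-receptors, was the 1 called gene, with 8.36 ± 3.42 in HSF-6(8) and 94.6 ± 24.9 in HSF-6(S9) (2.17 ± 0.20, limma adjusted p = 0.0174, n = 3 arrays). Untreated HSF-6(8) cells had 29.0 ± 4.27, and all of these signals are near or below the array median. Without the first or second control array, any of the treated HSF-6(8) arrays, or the second or the third HSF-6(S9) array, CFC1B was not called (adjusted p from 0.0646 to 0.177). Counting limma p under 0.05 without adjustment, 348 genes differed where 675.8 would by chance, and 864 genes had groups that did not overlap (6.39%, against 10% by chance). These chance values hold for arrays that vary independently. The third arrays of the treated sublines varied together (r = 0.25), which can lower both counts, so the shortfall does not show that the sublines are alike. For 10499 of the 13516 genes (77.7%) the 95% interval of the difference lay within 2-fold, so for the others a 2-fold difference was not excluded. With only the first and second arrays of each group, CFC1B had an adjusted p of 0.336, with 64 added to each value 0.357 (log2 fold change 1.12), and with the third arrays as a batch block 0.0194. In simulated data with independent arrays, this comparison recovered 29.3% of 2-fold and 85.8% of 4-fold changes, which may overstate recovery in the real arrays.

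Genes of TGF-beta, Nodal, BMP and FGF responses were lower as a group in treated HSF-6(S9), with a median of -0.31 over 29 members (camera adjusted p = 0.00115; adjusted p = 0.511 with an estimated correlation). Endoderm markers had a median of -0.41 (camera adjusted p = 0.0108; adjusted p = 0.611 with an estimated correlation) and naive state markers of -0.36 (0.0261; adjusted p = 0.511 with an estimated correlation). Glycolysis genes had a median of 0.18 (0.0261; adjusted p = 0.674 with an estimated correlation). Fry called none of these 4 lists (adjusted p from 0.316 to 0.678), and with no filter on low values endoderm (camera adjusted p = 0.0961) and naive state markers (0.231) were not called. With the 75th percentile filter endoderm (0.414), naive state (0.112) and glycolysis genes (0.0857) were not called, glycolysis also not with quantile normalization (0.472), nor naive state (0.789) and TGF-beta responses (0.557) with only the first and second arrays. In all 4 lists 0 members were called, also when adjusted over the list alone. Their largest values were -1.43 ± 0.96 for CER1, a secreted Nodal antagonist, -1.20 ± 0.63 for GATA6, -0.93 ± 0.31 for DUSP4, -1.0 ± 0.63 for GDF3, -0.93 ± 0.85 for ALPG and 0.43 ± 0.31 for PFKM, each with adjusted p = 0.989. The third treated HSF-6(8) array had 4489 for CER1 against 188 and 234 on the others, and without it none of these lists was called. All 4 medians then shrank, to -0.18 for TGF-beta responses (camera adjusted p = 0.228), -0.04 for endoderm (0.788), -0.06 for naive state (0.57) and 0.08 for glycolysis (0.158). The endoderm list was also not called without the first HSF-6(S9) array (0.275), nor the naive list without the first or the third (0.108 and 0.181). Glycolysis was not called without the first treated HSF-6(8) array (0.0754) and turned to a median of -0.02 without the second HSF-6(S9) array (0.751).

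The other 26 lists were not called between the treated sublines, and 0 of their members were called, also when adjusted over each list alone. X-linked genes had the largest single value, 1.65 ± 0.28 for LOC105373383 (adjusted p = 0.989), and PNCK had 1.28 ± 0.55. Lineage genes had 1.33 ± 0.83 for DLK1, an imprinted gene of neuroectoderm, -1.21 ± 0.75 for TBXT and -1.20 ± 0.81 for EOMES, the latter pair being transcription factor genes of the primitive streak. SOX2 differed by 0.37 ± 0.26, NANOG by -0.17 ± 0.25, EZH2 by -0.15 ± 0.31, AHCY by 0.27 ± 0.22, HDAC1 by 0.10 ± 0.21 and DNMT3B by 0.11 ± 0.25. Among the lists, fibroblast and stromal markers had an adjusted p of 0.238 and changed direction with a single array. They were lower without the first or second treated HSF-6(8) array (median -0.33, adjusted p = 0.0048; -0.38, 0.0212) or the third HSF-6(S9) array (-0.23, 0.0143), and higher without the third treated HSF-6(8) array (0.23, 0.0321). With an estimated correlation these 4 calls were lost (adjusted p = 0.597, 0.709, 0.663 and 0.471), as they were by fry (0.569, 0.688, 0.624 and 0.717). Metallothioneins were lower without the second HSF-6(S9) array (-0.71, 0.000174; adjusted p = 0.393 with an estimated correlation), against -0.48 and an adjusted p of 0.125 with all arrays. Leaving out that same array also brought in pluripotency (-0.28, 0.0147), neuroectoderm (0.44, 0.0222) and cholesterol synthesis genes (0.14, 0.0367), with adjusted p = 0.536, 0.536 and 0.427 with an estimated correlation. Histone methyltransferases and demethylases (0.15, 0.0453) came in without the first treated HSF-6(8) array, histone genes (0.23, 0.0154) without the third, and trophoblast markers (-0.16, 0.0476) without the third HSF-6(S9) array, with adjusted p = 0.618, 0.513 and 0.588 with an estimated correlation. Fry called none of the lists that came in without a single array (adjusted p from 0.29 to 0.717).

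The third comparison, treated HSF-6(S9) against untreated HSF-6(8), mixes subline and treatment, since the series has no untreated HSF-6(S9). It gave 120 genes higher and 38 lower. ZNF682 (4.98 ± 0.30, and 6.51 or 3.45 with 1 or 64 added to each value), NNAT (3.94 ± 0.31) and DPPA5 (3.97 ± 0.57, adjusted p = 0.0138) had the largest rises with 16 added, an order that depends on that number: ASTE1, chosen after its values were seen, went from 3.30 ± 1.70 to 232 ± 111. MBD3L2 fell by 3.56 ± 0.20 on the log2 scale (-5.91 with 1 and -2.01 with 64 added) to 2.6 ± 1.57, GRPR fell by 3.26 ± 0.23 to 60.8 ± 7.81, and LCP1, which encodes an actin-bundling protein, fell by 2.80 ± 0.44 from 452 ± 94.8 to 51.3 ± 13.6 (limma adjusted p = 0.0199, n = 3 arrays). LCP1 lost its call without any control or HSF-6(S9) array (adjusted p from 0.0521 to 0.0763), and DPPA5 without the second or the third control array or the second or the third HSF-6(S9) array (0.0511 to 0.054).

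Of the genes called in the first comparison, 82 of the 101 higher and 10 of the 13 lower were called the same way here, and 0 the opposite way. Independent calls would share 0.897 and 0.0365 genes, and unchanged groups simulated with shared controls shared 0.01 on average and at most 1. With no changed gene, such groups give few calls that could be shared. The simulated count therefore does not measure how much shared controls add to the overlap of real calls. Across genes, which are not independent replicates, the correlation of the fold changes was 0.805, against 0.50 in the simulations, and the covariance was 0.175 against 0.0512. Part of the observed overlap may come from the shared controls, which could not be split into independent sets. Of the 114 genes, 113 differed by less than 2-fold between the treated sublines, and for 79 the 95% interval of that difference lay within 2-fold. The overlap of 92 fell to 51, 46 and 51 without the first, second and the third control array, to 50 and 47 without the first and second treated HSF-6(8) array, and to 54 without the first HSF-6(S9) array.

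Camera called 7 lists here, against the same 3 control arrays as in the first comparison, so that lists called in both are not independent results. Neuroectoderm markers had a median of 0.84 (camera adjusted p = 0.000882; adjusted p = 0.261 with an estimated correlation), with PAX3 called at 3.34 ± 0.51 and 4 members when adjusted over the list alone, and a median of 0.37 with no filter on low values. The third HSF-6(S9) array had a neuroectoderm median of 1.59 over the control mean, against 0.57 and 0.78 on the other HSF-6(S9) arrays. Endoderm markers had 0.64 (0.000274; adjusted p = 0.611 with an estimated correlation), with the keratin gene KRT19 called at 1.11 ± 0.21 and 7 members when adjusted over the list alone. Cancer-testis genes had 1.93 (camera adjusted p = 0.00105, and 0.229 with an estimated correlation), with MAGEA8 called at 3.14 ± 0.29 and 3 when adjusted over the list alone. The MAGEA8 control signal of 11.3 ± 9.96 is so low that the size of this fold depends on the number added to each value. WNT genes had 0.30 (0.0059; adjusted p = 0.231 with an estimated correlation), with DKK1 at 3.86 ± 0.25 and LEF1 at 2.78 ± 0.50 called and 3 when adjusted over the list alone; the list was not called with the mean of a gene's probe sets (0.15, adjusted p = 0.0841) or the 75th percentile filter (0.25, 0.107). Germline genes had 1.54 (0.0229; adjusted p = 0.261 with an estimated correlation), with DPPA5 and TDRD12 called, and 3 higher and 1 lower when adjusted over the list alone. With no filter on low values, neither germline genes (0.16, adjusted p = 0.167) nor cancer-testis genes (0.02, adjusted p = 0.578) were called. The pluripotency network had -0.22 (0.0258; adjusted p = 0.611 with an estimated correlation), with 0 called and 1 lower when adjusted over the list alone, and LEFTY1 at -3.0 ± 0.68 (adjusted p = 0.076). Endoplasmic reticulum and oxidative stress genes had -0.20 (0.0296; adjusted p = 0.611 with an estimated correlation), with 0 called, also when adjusted over the list alone. The stress list was not called with no filter (adjusted p = 0.0535), the mean of a gene's probe sets (0.0841) or only the 2 groups compared (0.0574). With only the first and second arrays, stress (0.410), pluripotency (0.126) and germline genes (0.0514) were not called. Fry did not call endoderm (adjusted p = 0.259), pluripotency (0.356) or stress genes (0.316). LEFTY1 was called without the third treated HSF-6(8) array (adjusted p = 0.0017) and with the third arrays as a batch block (0.0408).

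Several of these calls were lost when any of several arrays was left out alone, which leaves fewer arrays to test. The pluripotency list was not called without the first control (median -0.26, camera adjusted p = 0.0513), first HSF-6(S9) (-0.29, 0.055) or the third HSF-6(S9) array (-0.07, 0.303). Only without the third HSF-6(S9) array did its median shrink from the -0.22 of all arrays. The stress list was not called without the third control (-0.24, 0.199), the third treated HSF-6(8) (-0.20, 0.0524), first HSF-6(S9) (-0.18, 0.0786) or the third HSF-6(S9) array (-0.11, 0.0649). KRT19 lost its call without any array but the third treated HSF-6(8) array (0.0653 to 0.115), and LEF1 without any but that and the third control array (0.0515 to 0.118). PAX3 lost it without any control array or the first HSF-6(S9) array (0.0514 to 0.0644). TDRD12 lost it without the second or the third control or the first or second HSF-6(S9) array (0.0611 to 0.0762).

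Other called list members were GATA3 (2.19 ± 0.21, trophoblast), ID3 (1.52 ± 0.20, mesoderm and TGF-beta responses), MACROH2A2 (2.15 ± 0.26, histones), NLRP2 (1.39 ± 0.23, imprinted) and ZEB1 (3.03 ± 0.48, adhesion). NLGN4X, a synaptic adhesion gene of the primed state list, fell by 1.10 ± 0.21 (adjusted p = 0.0414). It lost its call without any array but the third treated HSF-6(8) and first HSF-6(S9) arrays (0.0659 to 0.142), ZEB1 without the first or second control array (0.064 and 0.0647), and NLRP2 without the second control, first treated HSF-6(8) or any HSF-6(S9) array (0.051 to 0.0961). X-linked genes had 9 higher and 5 lower, with BEX5 at 3.51 ± 0.17 and TCEAL2 at 3.33 ± 0.26, and 15 and 7 when adjusted over the list alone (camera adjusted p = 0.379). The lists of trophoblast (0.139), mesoderm (0.196), stromal (0.379), imprinted (0.0678), histone (0.192), naive (0.665), primed (0.333), TGF-beta (0.139) and adhesion genes (0.459) were not called by camera, nor were the other 13 lists, which had 0 called members, also when adjusted over each list alone. Fry called the primed state list (adjusted p = 0.0212) and, among those 13, the DNA methylation and TET list (0.00079), both higher. With the third arrays as a batch block FN1 (adjusted p = 0.0403), UHRF1 (0.00655) and YAF2 (0.0266) were called higher and ACSM3 (0.0369) lower, and with no filter on low values the imprinted list was (0.0419; adjusted p = 0.624 with an estimated correlation; fry adjusted p = 0.0843). When adjusted over the list alone, trophoblast had 2 members higher, mesoderm 1, stromal 2, imprinted 3, histone genes 1 and adhesion 2, while naive had 3 higher and 1 lower, and primed and TGF-beta 1 each way. Single arrays brought in the lists of imprinted genes (0.0441 without the second control array), TGF-beta responses (0.0263 without the third treated HSF-6(8) array), trophoblast (0.0243), metallothioneins (0.0222) and proliferation (0.0303, each without the second HSF-6(S9) array), and glycolysis (0.0472) and adhesion (0.0341, each without the third). With an estimated correlation none of these 7 was called (adjusted p = 0.415, 0.255, 0.393, 0.589, 0.520, 0.663 and 0.485 in that order), and fry called trophoblast alone (0.006; 0.0540 to 0.534 for the others). SOX2 differed by 0.18 ± 0.26, NANOG by -0.66 ± 0.25, EZH2 by 0.25 ± 0.31, AHCY by 0.53 ± 0.22, HDAC1 by 0.36 ± 0.21 and DNMT3B by 0.17 ± 0.25, none of them called.

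The 158 called genes compare with 1909 at a limma p under 0.05 without adjustment, and with 2731 genes whose groups did not overlap (20.2%, against 10% by chance). The count was 240 without the third treated HSF-6(8) array, 68, 57 and 79 without the first, second and the third control array, 101 without the first treated HSF-6(8) array, and 105 and 73 without the second and the third HSF-6(S9) array. With the third arrays as a batch block it was 295, and within the first and second arrays alone it was 93. Leaving out the 3 arrays that stood apart, chosen after seeing the data, left 38.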

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

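The tests of the array labels, of a batch of the third arrays, of stromal cells and of the third treated HSF-6(8) array were chosen only after the result was seen.

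Outside the comparisons, a signal above the control arrays appeared in 7 of the 4553 kept probe sets that map to no gene or to several genes. These 7 were called higher in treated HSF-6(8) by the same limma test, and 0 were called lower.

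The first treated HSF-6(S9) array was close to the first treated HSF-6(8) array, with 188 genes more than 2-fold apart, where arrays of 1 group had between 266 and 1516. A single array deposited under both labels is excluded, since 0.00366% of the probe sets had equal values. A wrong label stays open: of the 100 genes that best separated the other treated arrays, the HSF-6(S9) array lay nearer the HSF-6(S9) mean in 31 (95% interval 22.1 to 41.0), 8 percentage points more than the HSF-6(8) array with 23 (15.2 to 32.5; exact paired p = 0.185). CFC1B, at 72.6 on this array and at most 12.3 on the treated HSF-6(8) arrays, and GRPR, at 65.8 here, 51.8 and 64.7 on the other HSF-6(S9) arrays and 135 to 147 on the treated HSF-6(8) arrays, go against a wrong label, but both were picked after their values were seen. Sublines that are alike after treatment would give the same result. The comparison of the treated sublines called 1 gene, but it includes this array and so cannot tell likeness from a wrong label.

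The endoderm list lay 1.51 above the other arrays of its group on the third treated HSF-6(8) array, and so did single genes of endoderm and primitive streak, chosen after their values were seen, with EOMES at 3419 against 255 and 337, MIXL1 at 1541 against 38.4 and 78.1, and SOX17 at 977 against 127 and 208, while the mesoderm and primitive streak list lay 0.45 above (9 of 15 members) and neuroectoderm -0.13, a list that lay 1.21 above on the third HSF-6(S9) array. A batch shared by the third arrays is excluded for the endoderm list, which lay at most 0.15 above in the other groups. It stays open for the mesoderm list, 0.27 and 0.46 above on the third control and HSF-6(S9) arrays, and for the stromal list, at -0.0247 and 0.40 there and 0.80 here. Fibroblasts or other stromal cells cannot be told apart from a change in the HSF-6 cells: the stromal list was higher here in 20 of 20 members and the endoderm list exceeded it by 0.71 (permutation p = 0.184, two-sided). COL1A1 was only slightly higher, at 10614 against 8829 and 8707, and does not decide between them. The third HSF-6(S9) array, with COL1A2 at 4474 and EOMES at 377, goes against such cells. COL1A2, at 4804 here against 1784 and 2175, and COL3A1, at 736 against 362 and 99.1, go with them. All of these are single genes. Spontaneous differentiation in that culture stays open as an untested explanation.

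Genes called higher in treated HSF-6(8) outnumbered those called lower by 101 to 13, which is 88.6% higher. Array scaling is excluded as the whole cause, since 85.4% were higher after quantile normalization. So is noise of dim probe sets, since 87.0% were with a pseudocount of 64. Both reruns kept the filter on low values, which counts more treated than control arrays. A gene with signal only in treated cells can therefore pass it more easily than a gene with signal only in controls. Of the 101 higher genes, 54 had a control mean below a typical array median. The calls were also rerun with no filter, but the share of higher genes in that rerun is not given here. Whether the filter adds to the excess of higher genes therefore stays open. Differentiated cells on the third treated HSF-6(8) array are excluded for most of the set, since 69 of the 101 genes (68.3%) were called higher without it, but the share of higher genes was then 74.6%. That the compounds raise more genes than they lower may be a biological explanation, as a hypothesis found and tested on the same data, and a difference between the cultures other than the compounds stays open.

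Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split of treated and untreated HSF-6(8) gave 114 genes and the highest other split 1, so that 1 of the 10 splits reached the real count. Between treated HSF-6(S9) and untreated HSF-6(8) the real split gave 158 genes and the highest other 0, again 1 of 10. Between the treated sublines the real split gave 1 gene and the highest other 1, so 3 of 10 splits reached it. One of those 3 put the third arrays of both sublines on the same side, with the second HSF-6(S9) array, and had 1170 genes at an unadjusted limma p under 0.05 against 348 for the real split. With the third arrays as a batch block the count between the treated sublines was 1, and with only the first and second arrays 0. In treated against untreated HSF-6(8) and between the treated sublines, 4 of the 10 splits, the real one included, put every 2 arrays of the same mark on opposite sides, and the highest of the other 3 had 0 genes.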

How the results depend on the processing

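The third arrays as a batch block, only the first and second arrays, array weights, and leaving out 3 arrays (first control, the third treated HSF-6(8), second HSF-6(S9), for spike-in signal or correlation within their group) were chosen after the data were seen. Main counts are given in the order treated against untreated HSF-6(8), treated HSF-6(S9) against treated HSF-6(8), treated HSF-6(S9) against untreated HSF-6(8), then shared calls: 114, 1, 158 and 92. With no filter the second to the fourth were 0, 96 and 61, of which the third kept 89 genes. The 75th percentile filter gave 65, 0, 98 and 54, with fewer genes tested. The second count was also 0 with a pseudocount of 64, every probe set on its own, eBayes with trend, and only the 2 groups compared, where the shared calls were 60. An adjusted p under 0.01 gave 43, 0, 41 and 37, and treat at 1.5-fold gave 42, 0, 43 and 39, both stricter by construction. The unmoderated test gave 0, 0, 0 and 0 at the thresholds of the main counts. The 1329, 348 and 1909 genes at an unadjusted limma p under 0.05 come from the moderated test with no fold minimum. They are therefore not a like count. Leaving out each array gave 52 to 118, 0 to 1, 57 to 240 and 46 to 106. The third arrays as a block gave 191, 295 and 155 for the first, the third and the fourth and kept all 114 and 158. Only the first and second arrays gave 0 and 93 for the second and the third, array weights gave 497, 448 and 307 without the second, and leaving out 3 arrays gave 35, 0, 38 and 28. The weight of the second control array was 8.14, against 0.939 and 0.354 for the first and the third control. The control values of the weighted fit thus rested mostly on that array. The replicate block gave 162, 1 and 254 for the first to the third count and lost 9, 0 and 7 of the calls. Arrays of the same mark correlated above 0.1 in the first and second comparison, and in the third comparison only the third arrays did (r = 0.34). Of the 9 arrays 3, the third ones, correlated best with their own mark. Where no reason is given, the cause was not tested.

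Called lists numbered 7, 4 and 7. An estimated correlation gave 0, 0 and 0, and fry 0 for the second. The second was 2 with no filter, 1 with the 75th percentile filter, where the first was 4, and 1 with only the first and second arrays; leaving out each array gave 6 to 9, 2 to 7 and 5 to 10. Between treated sublines the endoderm list reversed in test direction without the third treated HSF-6(8) array (median -0.0359) and with only the first and second arrays (-0.0312), and glycolysis without the second HSF-6(S9) array (-0.0188) and leaving out 3 arrays (-0.0996). Leaving out each array gave medians of -0.674 to -0.0359 for endoderm and -0.0188 to 0.319 for glycolysis. The cause was not tested. The 75th percentile filter left some lists with no tested gene and so no value. Of the other results of named genes, 1831, 1744 and 1452 kept direction and side of the threshold, 177, 17 and 120 lost the call, and 38 and 36 gained one in the first and the third comparison. Of lists, 675, 671 and 675 kept both, 21, 26 and 27 lost the call and 23, 18 and 17 gained one. Dim signal limits the values: 53.5% of the genes that rose had a control mean below the array median, against 6.35% of all tested genes, and in simulated data the first comparison recovered 25.8% of 2-fold and 86.2% of 4-fold changes.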

Other observations

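Tests of neighbouring genes, of chromosome 20 and of zinc finger genes were chosen only after the result was seen, and so were the genes named here.

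In treated HSF-6(8), the neurofilament genes NEFL and NEFM rose by 3.03 ± 0.25 and 3.00 ± 0.31, and GAD1, which encodes the enzyme that makes the transmitter GABA, by 3.16 ± 0.25 from 60.6 ± 5.79 to 688 ± 198. WLS, which encodes the carrier for WNT secretion, rose by 3.08 ± 0.35, the WNT enhancer gene RSPO3 by 2.39 ± 0.30 and ENPP2, which encodes the enzyme that makes lysophosphatidic acid, by 2.95 ± 0.19. These are single genes, and no list that holds them was tested. In treated HSF-6(S9) against the same controls these 6 genes were called as well, and in both comparisons all of them kept their call with any 1 array left out.

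In 6 cases, genes called higher in treated HSF-6(8) were next to each other among tested genes, against 0.752 on average and 6 at most in 10000 random sets (permutation p = 4e-04). The pairs were ZNF682 with ZNF626, EPHA4 with PAX3, CST4 with CST1, CST1 with CST2, NEFM with NEFL, and TCEAL2 with BEX5. There were 3 pairs without the second control, the third control or the first treated HSF-6(8) array, 4 without the first control or the second treated HSF-6(8) array, and 5 without the first HSF-6(S9) array. EPHA4 and PAX3 lost their call without any control, any treated HSF-6(8) or the first HSF-6(S9) array (adjusted p from 0.0534 to 0.132), CST4 without the second or the third control or any treated HSF-6(8) array (0.0585 to 0.0846), and CST2 without any control or the first treated HSF-6(8) array (0.0533 to 0.0731). A shared change of neighbouring genes is a candidate explanation for these 6 pairs, but most are paralogs, and probes that bind the RNA of both members could give the same result, which was not tested.

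Chromosome 20 held 10 of the genes that rose among 392 tested, where 2.93 would be expected (Fisher exact p = 0.000689, adjusted p = 0.0158 over 23 chromosomes). It held 4 without the second control, the third control or the first treated HSF-6(8) array (Fisher exact p = 0.0749, 0.0710 and 0.0872, not adjusted), 5 without the first control or the second treated array (0.0336 and 0.0103), and 6 without the third treated array (0.0425). The genes that rose there include the neighbours CST4, CST1 and CST2, whose probes might bind the same RNA. Fisher's test counts them as separate genes, so its p may be too small. An extra copy of the whole chromosome in the treated culture is excluded, since the median log2 fold change of its genes was 0.036 where 3 copies against 2 give 0.58. For the part from HM13 to DNMT3B the median was 0.16 (quartiles 0.03 and 0.44) over 19 genes, of which ASXL1 was the 1 called. This lies below 0.58 and argues against an extra copy of that part in all cells. No interval of the median was computed, and fold changes of dim genes are understated, so such a copy is not strictly excluded. ASXL1 lost its call without any array but the second and the third HSF-6(S9) arrays (adjusted p from 0.0740 to 0.138). A copy in part of the cells could stay below these values and was not tested.

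Zinc finger genes named ZNF numbered 5 among the genes that rose and 417 among those tested, where 3.12 would be expected (odds ratio 1.64, 95% interval 0.519 to 4.0, Fisher exact p = 0.243). A shared response of zinc finger genes as a class was thus not shown, though the interval leaves room for one.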
